A study of Drosophila melanogaster with 2 samples.

How the data were processed

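The material was whole Drosophila melanogaster embryos of mixed sex, collected 0 to 24 h after egg laying, from a strain in which an exon coding for enhanced GFP sits in an intron of luna, so that the gene makes a fusion of its protein with GFP. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP, and the libraries are 2 biological replicates of this 1 group. The labels name a possible control experiment, which was not analysed here. There is no other condition, so each comparison is made between classes of regions or genes within the peak lists, or between both replicates.

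The starting point was 8 peak lists in narrowPeak format. For each of the builds dm6 and dm3 there was 1 candidate list per replicate, 1 candidate list of both replicates pooled and 1 list of peaks that passed the irreproducible discovery rate (IDR) threshold, a cut on how well the ranks of peaks repeat between replicates. Per the deposited README texts, the candidate lists were derived from alignments together with a control file, the pooled list from the alignments of both replicates, and the IDR list from both replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR cut are not given in the sources used here. The authors deposited a signal value for each peak, treated here as a score without a stated scale, which served to describe, rank or filter peaks within a list and to correlate the replicates. The authors also deposited a q value on the −log10 scale for each peak, which stands at its ceiling of 3.57 in every IDR peak and was therefore not used to rank them. The summit is the offset deposited with each peak. Read counts were not used here, so the depth of each library is unknown, and no list was called higher or lower in signal than another.

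The IDR list in dm6 held 1696 peaks, and these were exactly the 1696 strongest of the 21725 pooled candidates. A comparison of IDR peaks with candidates that did not pass is therefore a comparison of strong with weak candidates. Each replicate list in dm6 held 30000 candidates, the same round number in both.

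Genes, transcription start sites (TSSs) and exons were taken from Ensembl release 115 for the genome build BDGP6.54, which has the coordinates of dm6, and sequence was taken from the RefSeq copy of the Release 6 assembly. 0 peaks reached beyond the end of an arm in that assembly. The dm3 lists were used for counts alone, and no coordinate was converted between builds. Transposable elements were left out, which left 18164 genes on the arms 2L, 2R, 3L, 3R, 4 and X, of which 13945 were protein-coding, with 23584 distinct TSSs. Coordinates are 1-based in dm6.

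A summit within 500 bp of a TSS of any annotated gene was called a promoter summit, and other summits were given the first class that applied in the order 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic. Classes were compared between IDR peaks and pooled candidates overlapping no IDR peak with two-sided Fisher's exact tests. A protein-coding gene counted as having a promoter peak when an IDR summit lay within 500 bp of a TSS of that gene. There were 33 gene lists, each compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Of 1247 symbols given in the lists, 8 were not matched to the annotation used here. The name patterns of a list can take in a gene of another kind, and this is stated where it mattered.

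Motifs were counted as present or absent on either strand in windows of 201 bp around each summit. The main control was the window centred 1000 bp to the right of the same summit, with an exact two-sided McNemar test on pairs in which 1 window alone held the motif. A further control was a window at the same distance from a random TSS of a protein-coding gene without a promoter IDR peak. The KLF core CACRCCC was tested alone, 22 other motifs were adjusted together, and all 2080 pairs of a 6-mer and its reverse complement were adjusted together.

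For the replicates, the candidate with the summit nearest to each IDR summit within 250 bp was taken from each list, and Spearman's rho and Pearson's r on log10 signal were computed across peaks with permutation tests of 100000 resamples. The strongest 1696 candidates of each replicate were compared by overlap of at least 1 bp, against 1000 circular shifts along each arm. Intervals of shares are Wilson 95% intervals and those of odds ratios are Woolf 95% intervals. Peaks and genes are not biological replicates, so p-values describe these lists and not the spread between embryos, and the intervals cover counting error only.

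The named genes are luna, the genes of the 20 strongest IDR peaks, up to 4 members with the strongest promoter peak of each list past the adjusted threshold and of the KLF, segmentation, Hox and mitotic lists, and the 5 strongest candidates of each replicate that overlap no IDR peak. A peak took the name of the nearest protein-coding TSS within 2000 bp, and otherwise of the gene around the summit. The tests, lists, motifs, naming rule and most alternatives were fixed before the data were examined. The alternatives were the dm3 list, the IDR peaks at or above the median signal, each replicate alone, promoter windows of 250 and 1000 bp, overlap of the whole interval, other gene sets, other control windows and other matching distances. The comparison of classes outside promoters was added after the data were seen.

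The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. All of 1000 peaks planted at TSSs were called promoter peaks, against 13.2% of 696 peaks placed at random. All of 10 planted gene lists and 0 of 190 random lists passed an adjusted p of 0.05. A motif planted in 170 sequences was found in 170, and it was found in 6 of 1696 random control sequences. A correlation of 0.5 over 1696 simulated pairs was recovered as 0.494.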

Results

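Binding of the luna-GFP fusion was measured by chromatin immunoprecipitation and sequencing in whole embryos of Drosophila melanogaster. The gene luna encodes a zinc finger transcription factor of the KLF family. The libraries were 2 biological replicates of 1 group, and the design asks where in the embryonic genome the fusion protein was recovered. The IDR list in dm6 held 1696 peaks, with signal values from 46.4 to 689 and a median of 64.7. The dm3 list held 1639. Depth is unknown, and each signal value is the authors' own score of a peak.

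At luna itself the signal was modest. The gene lies on the minus strand of 2R from 10977956 to 11116378 and spans 138 kb, with 2 annotated TSSs at 11106816 and 11116378. A single IDR peak fell within the gene and 5 kb around it, at 2R 11062882 to 11063257, in an intron and 43746 bp from the nearest luna TSS. It had a signal of 53.7 and ranked 1243 of 1696. The nearest candidate ranked 764 of 30000 in replicate 2 with a signal of 37.7, and 2265 of 30000 in replicate 1 with a signal of 19.1. In replicate 1 alone this region would thus not be among the 1696 strongest. The region held 27 pooled candidates in all. Within 1000 bp of a luna TSS the strongest pooled candidate, in the 5′ UTR, ranked 4373 of 21725 with a signal of 29.6.

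**Figure D1:**
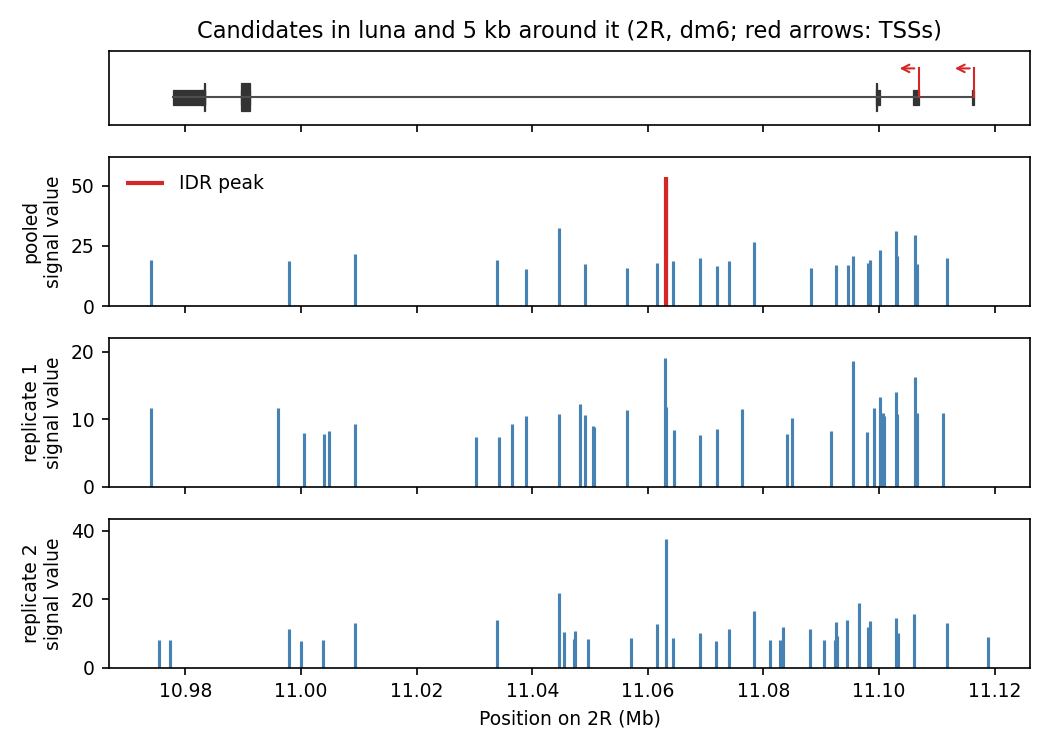
Candidates in luna and 5 kb around it on 2R in dm6, with the gene model on top (thick bars coding, thinner bars untranslated, red arrows TSSs) and the authors' signal value of each candidate against its summit position in Mb for the pooled list and each replicate. The only IDR peak, in red, is the intronic one with a pooled signal of 53.7.

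The strongest peaks lay mostly within 500 bp of a TSS. The highest signal, 689, was at X 2703754 to 2704041, with its summit 43 bp upstream of the TSS of Ugalt, a Golgi transporter of UDP-galactose. The next was at 3L 19590469 to 19590782, 100 bp upstream of CG14100, with a signal of 672. A signal of 586 was found at 2R 15217601 to 15217910, 143 bp upstream of mRpL41, which encodes a mitochondrial ribosomal protein. The fourth lay at 2L 480943 to 481244, 1402 bp upstream of cbt in intronic sequence, with a signal of 560. The gene cbt codes for another KLF-type zinc finger factor. CG11050 carried a peak of 519 in an intron at 2L 6612556 to 6612839, 1041 bp downstream of its TSS. The peak of 493 at X 12751216 to 12751569 lay in an exon of the long non-coding RNA gene lncRNA:Vinr.

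The other peaks among the strongest 20 were assigned to PNPase, Lk6, px, CG9663, CG32772, CenG1A, CHMP2B, CG1888, larp, CG31145, ph-p, Pdrg1, Chro and CG7601. Each took 1 name only, and the peak named for CenG1A also lies at the promoter of mRpS23, a mitochondrial ribosomal protein gene. PNPase encodes polynucleotide phosphorylase, Lk6 a protein kinase, CHMP2B a subunit of the ESCRT-III membrane remodelling complex, and larp a La-related RNA-binding protein. The summit at ph-p, a Polycomb group gene, lay 483 bp upstream of the TSS with a signal of 325. The summit at Chro, which encodes the chromodomain protein Chromator, lay 98 bp downstream in the 5′ UTR with a signal of 319. Of these 20 summits, 14 lay within 500 bp of the TSS named and 12 of the 14 were upstream of it. In both replicates 19 of the 20 ranked 30 or better, and the lowest rank was 35, for CG7601 in replicate 2.

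The replicates ranked the strongest regions alike and diverged further down. A candidate was found in both replicates for 1689 of the 1696 IDR peaks. The IDR list is exactly the 1696 strongest pooled candidates, so pooled signal separates its peaks from the rest. A single peak in it need not rank alike in both replicates. The replicate lists reach down to much weaker candidates. Presence in both is thus largely given for peaks of strong pooled signal, and the correlation describes this selected set only. Across these peaks Spearman's rho was 0.49 and Pearson's r on log10 signal was 0.64 (permutation p = 1e-05 for both, two-sided, the smallest that 100000 resamples can give). The log2 ratio of the matched signals had an SD of 0.61 across peaks. Of the 1696 strongest candidates of replicate 1, 1079 or 63.6% overlapped one of the 1696 strongest of replicate 2 (95% interval 61.3 to 65.9). Circular shifts gave 0.919% on average and at most 1.71% (permutation p = 0.001, one-sided, the smallest that 1000 shifts can give). For the strongest 212 of each the share was 72.2%, and for the strongest 3392 it was 57.1%.

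**Figure D2:**
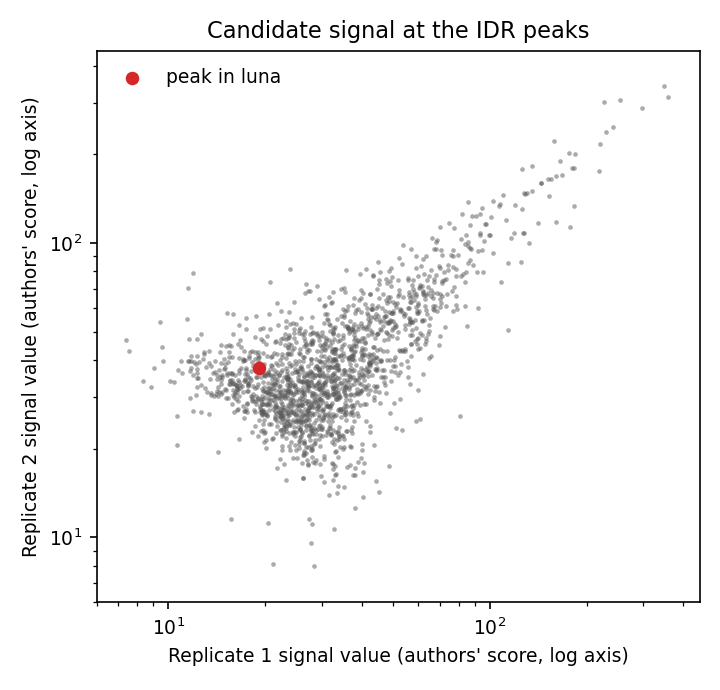
Signal value of the matched candidate in replicate 1 against replicate 2 for the 1689 IDR peaks found in both, on log axes, with the peak in luna in red. The relation is tight for the strongest peaks and broad below a signal of about 100 (rho 0.49 over all).

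Some strong candidates of a single replicate overlapped no IDR peak. Those named here had pooled ranks from 1749 to 2672 of 21725, below the cut at 1696 but not far from it. In replicate 1 the strongest was 222 bp upstream of Rcd2, at 3L 20540457 to 20540820, with rank 498, a signal of 38.5 and no candidate within 250 bp in replicate 2. It was followed by candidates at asl, which encodes the centriole protein Asterless, Pcyt1, S6KL and lncRNA:CR44363, with ranks from 609 to 659. The nearest candidates in replicate 2 ranked 23652 at asl, 18396 at Pcyt1 and 21702 at S6KL, and lncRNA:CR44363 had none within 250 bp. In replicate 2 the strongest was in the 5′ UTR of scyl at 3L 11252309 to 11252688, 192 bp from the TSS, with rank 515, a signal of 45.0 and no candidate within 250 bp in replicate 1. Candidates at Pak3, CG6770, snRNA:U5:63BC and GATAd followed, with ranks from 585 to 652 and ranks of 3558, 15693, 9150 and 9256 in replicate 1. Of the strongest 1696, 38 of replicate 1 and 85 of replicate 2 overlapped none of the 30000 candidates of the other replicate.

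Promoters held most of the IDR peaks. A summit within 500 bp of a TSS was found for 1122 of 1696 peaks, or 66.2% (95% interval 63.9 to 68.4). Among the 19765 weaker candidates the share was 30.5%, an odds ratio of 4.46 (95% interval 4.01 to 4.95, Fisher's exact test, p = 3.96e-183). Peaks shifted along the arms had a mean share of 13.6%. The summits sat upstream of the TSS. Of 1082 within 500 bp of a protein-coding TSS, 81.4% were upstream, and the median position was 75 bp upstream. The 200 bp directly upstream of protein-coding TSSs held 702 peaks, and the first 200 bp downstream held 163.

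**Figure D3:**
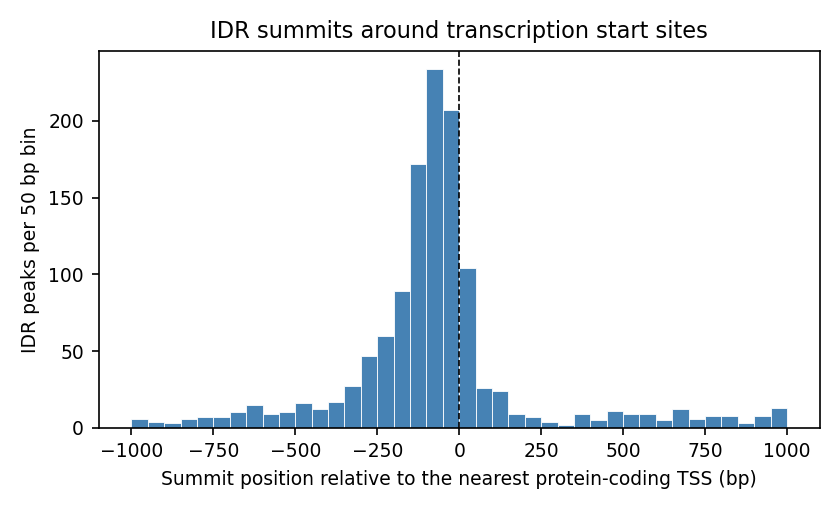
Number of IDR summits per 50 bp bin against the distance from the nearest protein-coding TSS in bp, negative values being upstream and the dashed line the TSS. The summits gather just upstream, with 702 peaks in the 200 bp before the TSS against 163 in the 200 bp after it.

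Away from promoters most IDR peaks lay in introns. Introns held 412 of the 574 IDR peaks outside promoters, or 71.8% (95% interval 68.0 to 75.3), against 54.2% of the weaker candidates outside promoters, an odds ratio of 2.15 (95% interval 1.79 to 2.59, Fisher's exact test, adjusted p = 1.05e-16). Coding exons held 7 IDR peaks or 1.22%, against 15.8%, an odds ratio of 0.066 (95% interval 0.031 to 0.138, Fisher's exact test, adjusted p = 2.17e-31). The 3′ UTR class was lower as well, with 12 IDR peaks or 2.09% against 5.49% (Fisher's exact test, adjusted p = 0.000264). Intergenic sequence, with 126 IDR peaks or 22.0% against 21.3%, did not pass, nor did the 5′ UTR with 6 and non-coding exons with 11 (Fisher's exact test, adjusted p = 0.716, 0.239 and 0.239). This comparison outside promoters was chosen after the data were seen. Its shares are parts of a whole, so lower shares of coding exons and 3′ UTRs raise the others, introns included. How much of the intron difference would remain without those 2 classes was not tested. Over all summits 5 classes were lower among IDR peaks, introns with 24.3% against 37.7% and intergenic sequence with 7.43% against 14.8% included, but those shares are bound to fall as that of promoters rises.

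Within the IDR list, promoter peaks had a median signal of 66.2 and other peaks 61.1, a difference of 0.116 in median log2 signal (permutation test, p = 0.00068, two-sided). The call was lost under 3 of 6 alternatives, with a difference of 0.0451 among the stronger 848 peaks, 0.0341 among the strongest candidates of replicate 2 alone and 0.0554 with a promoter of 250 bp (permutation test, p = 0.476, 0.267 and 0.066). The strongest 25% of the list held 299 promoter peaks of 424 and the weakest 25% held 270 (70.5% against 63.7%, Fisher's exact test, p = 0.0406). That call was lost under 4 of 6 alternatives, at a difference of 4.48 percentage points without replicate 1, 2.12 with a promoter of 250 bp, 3.77 among the stronger 848 peaks and 6.13 with any overlap of the interval (Fisher's exact test, p from 0.0584 to 0.579).

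By arm, IDR peaks numbered 413 on 3R, 349 on 3L, 338 on 2R, 302 on 2L, 286 on X and 8 on chromosome 4. The density was 12.1 peaks per Mb on X, between 12.4 and 13.4 on the major autosome arms, and 5.93 on chromosome 4. The X held 16.9% of the peaks on X and the major autosome arms (95% interval 15.2 to 18.8), and 17.8% of their length (exact binomial test, p = 0.39). No difference between X and autosomes was thus detected in the IDR list, and with TSSs as the reference the expected share was 16.7% (exact binomial test, p = 0.794). Mixed-sex embryos carry fewer copies of X than of autosomes, which was not adjusted for. The pooled candidates, which were not tested, numbered 141 per Mb on X against 161 to 173 on the major autosome arms.

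Genes for cytoplasmic ribosomal proteins had promoter peaks far more often than other genes. Of 86 ribosomal protein genes, 56 or 65.1% had an IDR summit at the promoter (95% interval 54.6 to 74.3), against 10.4% of other protein-coding genes. The odds ratio was 16.1 (95% interval 10.3 to 25.2, Fisher's exact test, adjusted p = 3.05e-32). Among genes with a pooled candidate at the promoter it was 8.27 (95% interval 5.07 to 13.5, Fisher's exact test, adjusted p = 8.89e-18). The 56 genes had 56 different peaks, and 27 of them were in the strongest 25% of the list. The strongest were at RpS27, with a signal of 235 and rank 41, RpL32 with 196 and rank 62, RpL23A with 187 and rank 67, and RpL14 with 183 and rank 75. Of all 13945 protein-coding genes, 1493, or 10.7%, had a promoter peak.

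Hippo pathway genes, which control tissue growth, were the other list above the remaining genes, with 6 of 15 members (40.0%, odds ratio 5.58, 95% interval 1.98 to 15.7, Fisher's exact test, adjusted p = 0.0262). These were kibra with a signal of 88.5, Mer with 76.0, the kinase gene hpo with 70.7 and mats with 58.2, followed by ex and yki. The result rested on few genes, and the call was lost under 6 of 8 alternatives, which were replicate 2 alone with 4 of 15, replicate 1 alone with 5 of 15, the stronger 848 peaks, promoters of 250 and 1000 bp and genes with a pooled candidate (Fisher's exact test, adjusted p from 0.0567 to 0.407). It held with any overlap of the interval and with a summit anywhere in the gene (Fisher's exact test, adjusted p = 0.0374 and 0.0479).

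Of the 4 comparison lists of genes with narrow expression, 2 were lower than the remaining genes. The chemoreceptor list, whose name pattern also takes in the odorant-binding protein genes named Obp, had 2 of 230, at Ir60e and Gr63a with signals of 54.8 and 48.6 (0.870%, odds ratio 0.072, Fisher's exact test, adjusted p = 6.53e-08). Without replicate 2 it was 0 of 230, with an odds ratio of 0.018, and the odds ratio was 0.035 among the stronger 848 peaks, 0.045 with a promoter of 250 bp and 0.132 with a summit anywhere in the gene, each past the test. Cuticle protein genes had 1 of 96 (odds ratio 0.087, Fisher's exact test, adjusted p = 0.00423). That member, Cpr, had a signal of 54.6 and encodes a cytochrome P450 reductase, which entered the list through its name and is not a cuticle protein. Antimicrobial peptide genes had 0 of 25 and chorion, yolk and vitelline membrane genes 0 of 17, and neither list passed (Fisher's exact test, adjusted p = 0.379 and 0.58). Since 0 is the lowest count there is, both lists were too short for a lower call. The cuticle call was lost among the stronger 848 peaks (Fisher's exact test, adjusted p = 0.0552). Among genes with any pooled candidate at the promoter these lists shrank to 19 and 12 genes, with odds ratios of 0.386 and 0.298. That is too few for a call, since with 0 peaks the adjusted p would still have been 0.191 and 0.89 (Fisher's exact test).

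Neither the patterning lists nor the list of KLF and Sp factors, which includes luna itself, was called higher or lower. The gap and pair-rule segmentation list of 24 genes also takes in other patterning genes, fkh and cnc among them. Of the 24, 2 had a promoter peak, at fkh with a signal of 59.7 and cnc with 56.4 (Fisher's exact test, adjusted p = 1). The peak at fkh ranked 312 in replicate 2 and 9670 in replicate 1. Of 13 Hox genes and cofactors 0 had one (95% interval up to 22.8%, Fisher's exact test, adjusted p = 0.683). Of 11 KLF and Sp factors 2 had one, at cbt with a signal of 170, in addition to its stronger peak further upstream, and at CG3065 with 63.0 (Fisher's exact test, adjusted p = 0.683). A lower call was out of reach for these lists of 24, 13 and 11 genes, since even 0 of 25 antimicrobial peptide genes did not pass. The mitotic list had 7 of 36 members with a peak (19.4%, odds ratio 2.02, 95% interval 0.882 to 4.61, Fisher's exact test, adjusted p = 0.379). These 7 genes had 6 different peaks. The strongest were at the condensin gene SMC2 with a signal of 72.3, the kinase gene aurA with 68.2, the spindle checkpoint gene BubR1 with 59.4 and polo with 55.1. Mitochondrial ribosomal protein genes had a peak in 12 of 73 cases and oxidative phosphorylation genes in 12 of 80, and neither list passed (Fisher's exact test, adjusted p = 0.415 and 0.563). In all, 2 lists were higher and 2 lower of 33 tested, and 5 passed an unadjusted p of 0.05.

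**Figure D4:**
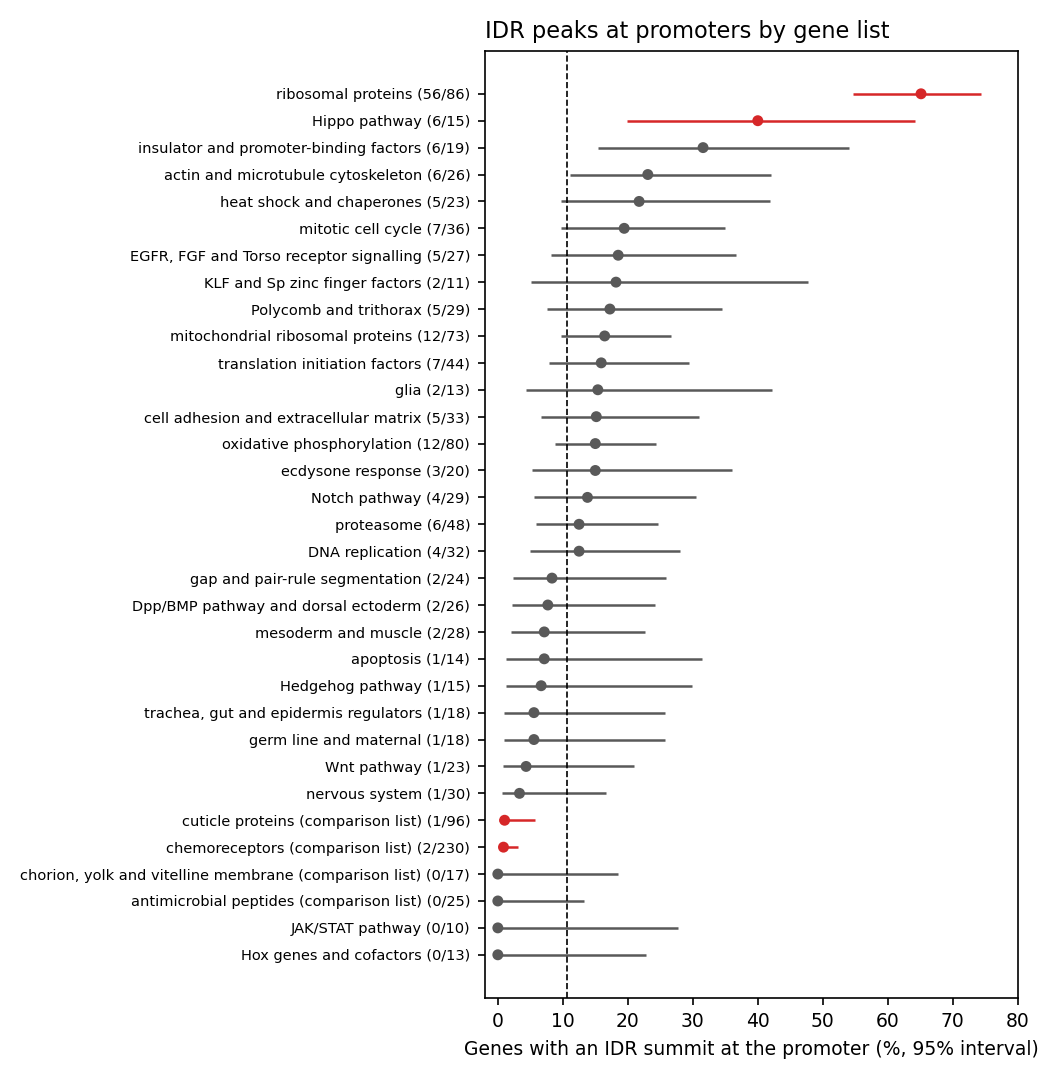
Percent of the genes of each list with an IDR summit within 500 bp of a TSS, with 95% Wilson intervals and the number of genes beside the list name, lists past the adjusted threshold in red and the share of all protein-coding genes, 10.7%, as a dashed line. Ribosomal proteins stand apart at 65.1%.

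The KLF core CACRCCC was not enriched at the summits. It was present in 41 of 1696 summit windows, or 2.42% (95% interval 1.79 to 3.26), and in 67 windows 1000 bp to the right, or 3.95%. The ratio of 0.61 was below 1 (exact McNemar test, p = 0.0138). To the left the control share was 5.37%, and the longer form CCMCRCCC had 1.47% at summits against 3.24%. Against windows matched on distance to a TSS, with 3.48%, the difference did not pass. It did not pass among the stronger 848 peaks or with 50 bp on each side of the summit either (exact McNemar test, p = 0.0725, 0.0649 and 0.0581 for the 3 in turn). The strongest and the weakest 25% of peaks had the core in 10 and 11 of 424 windows (Fisher's exact test, p = 1). The Sp-type motif GGGCGG was lower at summits as well, with 3.71% against 7.19% (exact McNemar test, adjusted p = 4.01e-05). That motif is all G and C, and summit windows had 38.1% GC on average against 43.7% to the right. It was not compared with windows of matched GC content, so base composition stays open.

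Of 22 other motifs, 6 were more frequent at summits and 4 less frequent after adjustment. A pair of CGATA elements, bound by the insulator protein BEAF-32, was present in 15.2% of summit windows against 3.71% of windows to the right (exact McNemar test, adjusted p = 1.6e-29). The element TATCGATA of the factor Dref was in 7.02% against 0.649%, the core promoter motif Ohler7 in 11.9% against 3.30%, a CTCF core in 2.71% against 0.413%, and the M1BP motif GGTCACACT in 2.00% against 0.295%. The Hox core TAATTA was in 14.7% against 11.4% (exact McNemar test, adjusted p = 0.0126). The CAGGTG E-box, the Pho core GCCAT and the CA repeat were, with the Sp-type motif, the less frequent ones. None of the 22 motifs was compared with windows of matched GC content. Base composition thus stays open for the less frequent motifs and for TAATTA. Other promoter motifs did not pass, among them the GAGA repeat GAGAGAG with 5.07% against 5.01%, the TATA box with 9.55% against 7.96%, Ohler6 with 0.649% against 0.177% and the initiator TCAGTY with 15.9% against 18.6% (exact McNemar test, adjusted p = 1, 0.157, 0.0971 and 0.0886). With 200 bp on each side of the summit GAGAGAG, the TATA box, CAGCTG and CACTTAA were called higher. With 50 bp on each side the TATA box was, and without replicate 2 the TATA box and Ohler6 (exact McNemar test, adjusted p from 4.37e-05 to 0.0496 over all of these). Against TSS-matched windows the CTCF core was at 0.531%, the Dref element at 3.48%, Ohler7 at 5.54% and the CGATA pair at 8.31%, each still below the summits. The M1BP motif, at 1.47% in those windows, lost its call, as did the Pho core at 31.2% and the CA repeat at 1.83% (exact McNemar test, adjusted p = 0.374, 0.335 and 0.405). Calls gained there were the initiator, lower at summits against 21.6%, and CATATG and CACTTAA, higher with 7.31% against 4.95% and 4.72% against 3.07% (exact McNemar test, adjusted p = 9.68e-05, 0.0106 and 0.0348). Without replicate 1 the Pho core, the CA repeat and the Hox core did not pass (exact McNemar test, adjusted p = 0.146, 0.396 and 0.0918). The Pho core with 50 bp on each side of the summit and the CA repeat with 200 bp on each side did not pass either (exact McNemar test, adjusted p = 0.134 and 0.716).

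Of 2080 6-mers, 371 were more frequent at summits than to the right and 601 less frequent. The first 4 by p were AAAATA, TTAAAA, AAAAAT and ATTTTA, and the next were TATCGA in 21.2% against 7.96% of windows, CGATAG in 16.6% against 5.01% and ACAGTG in 19.99% against 7.67%. The summit windows had 38.1% GC on average, and the windows to the right 43.7%. Against TSS-matched windows, with 41.6% GC, ACAGTG came first with 7.55% in the control (exact McNemar test, adjusted p = 4.27e-23).

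**Figure D5:**
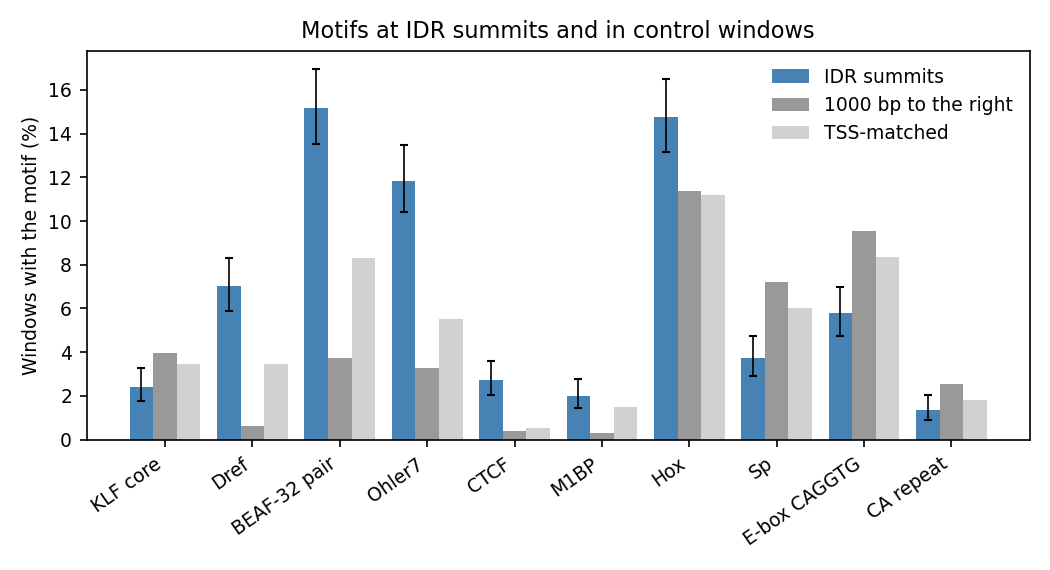
Percent of windows of 201 bp holding each motif at the IDR summits (blue, with 95% Wilson intervals), 1000 bp to the right (grey) and at TSS-matched points (light grey). The KLF core stands at 2.42% at summits against 3.95% to the right, while the Dref element stands at 7.02% against 0.649%.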

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

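The tests of rank noise, of regions missing from a replicate, of broadly expressed genes and of weak peaks in this part were chosen after the values were seen. Candidates were found on dm3 sequences outside the chromosome arms, which no comparison above used. They numbered 224 of 26185 in replicate 1 (0.855%, 95% interval 0.751 to 0.974), 106 of 29673 in replicate 2 (0.357%) and 56 of 18761 in the pooled list, and the IDR list held 0. The replicate lists differ in length and stand for 1 library each, so these shares describe the lists and show no difference between conditions. The strongest was on the heterochromatic sequence 3LHet with rank 797 in replicate 1, and each replicate had 1 on the mitochondrial genome.

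The KLF core, the sequence a KLF factor is known to bind, was less frequent at the summits of the luna-GFP peaks than 1000 bp away. The low GC content of the summits may account for part of this. Against windows 1000 to 4000 bp away with the same GC content the odds ratio was 0.753 (95% interval 0.499 to 1.14), an interval that holds both 1 and the unmatched odds ratio of 0.602, so this stays open. Control windows in another kind of sequence also stay open, since against TSS-matched windows the odds ratio was 0.687 (95% interval 0.459 to 1.03). Under dilution by weak peaks, the strongest 424 peaks would hold the core more often than their control windows. Their odds ratio was 0.578 (95% interval 0.262 to 1.28), and 10 of them held the core against 11 of the weakest 424. Neither value shows dilution, but so few windows with the core cannot exclude it. No biological explanation was tested.

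Ribosomal protein promoters had IDR peaks far more often than other promoters. The tables argue against a like signal at promoters of all broadly expressed genes, since the proteasome, oxidative phosphorylation, translation initiation and mitochondrial ribosomal lists together had 37 of 245 genes with a peak, or 15.1% (95% interval 11.2 to 20.1). Dref, M1BP and BEAF-32 motifs within 200 bp of the TSS were present in 57.0% of ribosomal protein genes and 35.3% of others, yet the odds ratio stratified by them was 14.0 (95% interval 8.83 to 22.3). Stratified by the number of TSSs it was 12.8 (95% interval 7.96 to 20.4). Neither the presence of these exact motifs nor the number of TSSs thus accounts for the excess alone. Motif presence is a coarse measure, since 35.3% of other genes have it too, so a part played by these factors stays open. Recovery of very active promoters without the fusion protein could also give this pattern and stays open, because no library lacking the fusion was analysed here, and no biological explanation was tested.

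Of the strongest 1696 candidates of each replicate, 617 were not among the strongest 1696 of the other. Of these, 45.9% in replicate 1 (95% interval 42.0 to 49.8) and 36.6% in replicate 2 (95% interval 32.9 to 40.5) overlapped a candidate of rank 3392 or better in the other replicate. This cannot decide on rank noise close to the threshold, because small differences in signal separate these ranks. In replicate 1 the signal was 21.9 at rank 1693 and 16.3 at rank 3395, and the log2 ratio between replicates had an SD of 0.61. Ranks of 848 or better in their own list were held by 114 of the 617 in replicate 1 and 138 in replicate 2. Of the candidates that were not shared, 6.16% in replicate 1 and 13.8% in replicate 2 overlapped none of the 30000 candidates of the other. Those lists reach down to signals of 7.32 and 7.71, so an overlap can be with a very weak candidate. The shares are therefore no upper limit for regions seen in a single replicate. Rank noise over a wider range was not tested, and a difference in depth stays open, because read counts were not used here.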

How the results depend on the processing

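Of 160 values under alternatives, 118 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. The cause was not tested for the others unless stated. The TSS-matched control for other motifs and 6-mers, the classes outside promoters, and each replicate alone for classes, luna, motifs and 6-mers, were chosen after seeing the data. Keeping 2L, 2R, 3L, 3R, 4 and X alone removed no peak and gave no value. Outside promoters 2 classes were lower, not 5, and introns were higher, since shares of a whole fall as another rises. No paired analysis was possible because there is a single group. The promoter share stayed above its background under all 7 alternatives, the ribosomal protein list stayed higher under all 8, and the replicate correlation and overlap passed under all of theirs. The peaks at or above the median signal, the upper part by signal, numbered 848 by construction. With them the calls for promoter signal, Hippo, cuticle proteins, the KLF core and strongest minus weakest promoter share were lost: the log2 signal difference of promoter peaks was 0.0451, the list count lower was 1, the odds ratios were 4.08 for Hippo, 0.0837 for cuticle proteins and 0.958 for mitotic genes, the KLF ratio was 0.576, and the strongest minus weakest promoter share was 3.77 points. A promoter of 250 bp ended 3 of these calls, at 0.0554 for the log2 signal difference, 3.79 for Hippo and 2.12 points. With 1000 bp the Hippo call was lost at an odds ratio of 4.69 and 1 list was higher, and with any overlap the call for the strongest minus weakest share was lost at 6.13 points. Among genes with a pooled candidate, fewer by construction, 1 list was higher and 0 lower, and the calls ended at odds ratios of 3.95 for Hippo, 0.386 for chemoreceptors and 0.298 for cuticle proteins, the last 2 lists being too short to pass there. With a summit anywhere in the gene 7 lists were higher. Against circular shifts 16 were higher and 0 lower, since shifted peaks fall at promoters less often than real ones. The X ratio turned from 0.954 to 1.01 with TSSs as the reference, neither past the exact binomial test. The KLF ratio did not pass with 50 bp on each side of the summit, at 0.571, or with a TSS-matched control, at 0.695. With 200 bp on each side of the summit 10 motifs were higher, and the TSS-matched control gave 242 6-mers higher and 345 lower. The strongest minus weakest KLF share was -0.236 points, and 0.472 with 50 bp on each side of the summit. Without replicate 1 the calls for promoter signal and its strongest minus weakest share were lost, and without either replicate that for Hippo. Without replicate 1 and without replicate 2, the log2 signal difference was 0.0341 and 0.0913, peaks at luna 1 and 0, lists higher 1 and 1, the Hippo odds ratio 3.09 and 4.32, motifs lower 2 and 4, the strongest minus weakest promoter share 4.48 and 9.91 points, and that of the KLF core 0.236 and -0.236 points. The unknown depth leaves open how many weak candidates would pass in deeper libraries.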

Other observations

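Of 19 insulator and promoter-binding factors 6 had a promoter peak, and the list did not pass the adjusted threshold (31.6%, odds ratio 3.86, 95% interval 1.47 to 10.2, Fisher's exact test, adjusted p = 0.0782). It passed under 3 of 8 alternatives, which were a promoter of 250 bp, the stronger 848 peaks and a summit anywhere in the gene (Fisher's exact test, adjusted p = 0.037, 0.0415 and 0.016). It did not pass under the other 5, which were each replicate left out, a promoter of 1000 bp, any overlap of the interval and genes with a pooled candidate (Fisher's exact test, adjusted p from 0.0904 to 1). Over the 8 the odds ratio ranged from 2.20 to 5.84. The members were named after their values were seen. They were Chro with a signal of 319, Trl with 108, Dref with 93.9, Cp190 with 76.5, BEAF-32 with 74.6 and pzg with 51.2. The peak at Dref is also the peak counted for RpL13. Of 29 Polycomb and trithorax genes 5 had a peak, and ph-p led with 325 ahead of Trl, brm, Sfmbt and Psc (Fisher's exact test, adjusted p = 0.58). Of 23 heat shock and chaperone genes 5 had one, led by Hsp83 with 131 (Fisher's exact test, adjusted p = 0.379).

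Promoter peaks and other peaks held different motifs. The Dref element was in 10.2% of 1122 promoter peaks and in 0.697% of 574 other peaks (Fisher's exact test, adjusted p = 4.82e-16), and Ohler7 in 16.6% against 2.61%. The E-box CATATG was in 5.61% of promoter peaks and 10.6% of others (Fisher's exact test, adjusted p = 0.00115). The CTCF core was in 2.05% of promoter peaks and 4.01% of others, which did not pass (Fisher's exact test, adjusted p = 0.0746). Genes for tRNA, snoRNA and rRNA had promoter peaks less often than protein-coding ones, with 2.41% of 290, 4.09% of 269 and 0 of 99 genes against 10.7% (Fisher's exact test, highest adjusted p = 0.000218). The other non-coding classes were ncRNA genes with 2.42% of 3261 and pseudogenes with 0.746% of 268, both lower, and snRNA genes, of which 3 of 32 had one (9.38%, Fisher's exact test, adjusted p = 1). These classes were not matched on the number of TSSs per gene or on how well reads can be placed. The shares thus describe where peaks were called and need not reflect binding.

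A hypothesis formed before the values were computed was that the promoter peaks lie between head-to-head gene pairs, in which another gene starts within 1000 bp on the opposite strand. Of 1082 IDR peaks within 500 bp of a protein-coding TSS, 496 or 45.8% were nearest to a TSS with such a partner. At points placed at the same distance from random protein-coding TSSs the share was 33.2%, an odds ratio of 1.70 (95% interval 1.43 to 2.03, Fisher's exact test, p = 2.1e-09). Among 5491 weaker candidates within 500 bp of a protein-coding TSS it was 30.6%, an odds ratio of 1.92 (95% interval 1.68 to 2.19, Fisher's exact test, p = 1.62e-21). The signal may thus favour head-to-head promoters. Whether this follows from their activity was not tested.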
